A study of Homo sapiens with 15 samples.

How the data were processed

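Biotin-labelled cRNA from 293T cells was hybridised to Illumina bead arrays, and 15 arrays in 5 groups of 3 were used: cells transfected with amiR-104, amiR-143, amiR-175 or amiR-268, and cells transfected with a non-targeting siRNA as the control. RNA was taken 48 hours after transfection. Replicates are separate transfections of 1 cell line, so p-values measure the spread between transfections. The deposited unnormalized values are summarized bead intensity per probe on a linear scale with no background subtracted, exported with GenomeStudio (version not given) per the submitters' processing notes. Each comes with a detection p-value, per the file headers. The authors' processed values are also intensity on a linear scale. A comparison with the unnormalized values found that they have the same sorted values on all 15 arrays to within 0.352 units (medians 154), which is what quantile normalization gives, with no sign of background subtraction, and no step is stated for them.

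The unnormalized intensities were analysed in R 4.3.3 with limma 3.58.1. Background was removed with neqc, which estimates it from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. A probe was kept when its detection p was under 0.05 on at least 3 arrays, which left 22545 probes. Gene symbols came from a table of human genes of assembly GRCh38.p14, used for names only: of all probes 30113 had 1 symbol (30074 matched by Entrez ID and 39 not), 8 had several and 17202 had none. Each gene was represented by its brightest kept probe among those with exactly 1 symbol, which gave 12395 genes, 3274 of them with more than 1 kept probe. PC had 4 probes, 3 of them kept. A planned result for a further gene is not reported here. Among called genes with several probes, a probe was called in the opposite direction for 21 of 831 genes with amiR-104, 39 of 1536 with amiR-143, 26 of 1124 with amiR-175 and 16 of 996 with amiR-268. Mean intensity per array ranged from 525 to 611 and probes detected from 18433 to 19769.

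A linear model with 1 mean per group was fitted to all 15 arrays with lmFit and eBayes (10 residual and 4.16 prior degrees of freedom, median moderated SD 0.176 on the log2 scale). Each amiR was compared with the control, as was the mean of the 4 amiRs, and the 6 pairs of amiRs were compared directly. P-values were adjusted with the Benjamini-Hochberg method over all genes tested within each comparison, and a gene was called changed at an adjusted p under 0.05. Where a group had no array with the probe above background, the fold was given as a bound. For PC an exact two-sided permutation test is given too, whose smallest p with 3 arrays against 3 is 0.1. Tested on simulated data for amiR-104 against the control, with 200 of 12395 genes changed, the procedure recovered 28.4% of genes changed by a log2 of 0.5, 95.5% of those changed by 1 and 100% of those changed by 2, with 8 false calls among 157. Far more genes were called in the real comparison (2797), and the simulated noise was drawn independently for each gene. These shares are therefore no direct measure of the recovery in the real data.

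The 26 gene lists (675 members, 538 tested, 49 with no probe of that name) cover metabolism, stress and innate responses, the cell cycle, the miRNA machinery and targets of endogenous miRNAs, and markers of other cell types. They were tested with camera at a preset correlation of 0.01, adjusted over the 130 tests of lists and comparisons with the control, and again with a correlation estimated per list. The same lists were also tested in the direct comparisons of amiRs, over 156 tests. Called genes were compared between amiRs beside the numbers that independent lists would share and beside 50 simulations of unchanged groups set against the same controls. The model, thresholds, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names PC, the 12 lowest and 8 highest genes of each amiR whose 3 arrays all lie on 1 side of the 3 control arrays, the 8 lowest and 8 highest of the mean with the same sign in all 4 amiRs, the 3 lowest and 3 highest of each pair of amiRs, the 5 with the largest mean change in each direction among genes called in all 4, and up to 4 members of each list with the smallest adjusted p. Symbols that are only provisional were not named. GAPDH, and genes described in the closing section, were chosen after their values were seen.

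The alternatives tried were other normalizations, an offset of 50, other detection filters, the mean of a gene's probes, only the groups compared, the replicate number as a block, other variance and weight settings, stricter thresholds and leaving out each array in turn. A search for seed matches was not run, since no transcript sequences were used here.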

Results

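Gene expression was measured on 15 Illumina bead arrays, each hybridised with labelled cRNA from 293T cells, a derivative of the human embryonic kidney line HEK293. The cells had been transfected with 1 of 4 artificial miRNAs (amiR-104, amiR-143, amiR-175 and amiR-268), short RNA duplexes designed to lower chosen transcripts as a miRNA does, or with a non-targeting siRNA that served as the control. RNA was taken after 48 hours, and each of the 5 groups held 3 replicate transfections of 1 cell line, so the p-values below measure the spread between transfections. Mean intensity per array ranged from 525 to 611, and between 18433 and 19769 probes per array were detected. Over the 12395 genes tested, arrays of 1 group correlated at 0.989 to 0.992 and arrays of different groups at 0.955 to 0.981. The number of arrays limits the precision. The first principal component held 33.2% of the variance and set the 3 amiR-143 arrays apart from the rest. The second held 19.5% and set the 3 amiR-175 arrays apart.

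The first question was whether the amiRs lowered PC, which encodes pyruvate carboxylase, the mitochondrial enzyme that makes oxaloacetate from pyruvate and a gene that the amiRs are understood to be designed against, although the labels do not say so. PC was lower in every amiR group. On its brightest probe the control level was 6.80 ± 0.22 (SD, n = 3) on the normalized log2 scale, and the levels were 5.68 ± 0.29 with amiR-104, 5.33 ± 0.19 with amiR-143, 4.82 ± 0.06 with amiR-175 and 5.01 ± 0.24 with amiR-268 (SD, n = 3 each). The log2 differences from the control were −1.12, −1.46, −1.97 and −1.78, each with a standard error of 0.16 and with limma adjusted p values of 0.000216, 6.71e-06, 7.66e-07 and 4.03e-06. The probe was not above background on any amiR-175 array, so that PC was at least 3.00-fold lower there, and it was detected on 3, 2 and 1 of the 3 arrays of amiR-104, amiR-143 and amiR-268. A second PC probe was at −0.79 (log2) with amiR-104 and, where it was not above background, at least 1.88-fold lower with amiR-143, 1.89-fold with amiR-175 and 1.88-fold with amiR-268, while another, which was not above background on any control array, gave −0.25, 0.15, 0.04 and −0.04 in the same order of amiRs and did not pass the test. An exact two-sided permutation test of 3 arrays against 3 gave p = 0.1 for each amiR on the brightest probe, the smallest value this design allows.

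**Figure D1:**
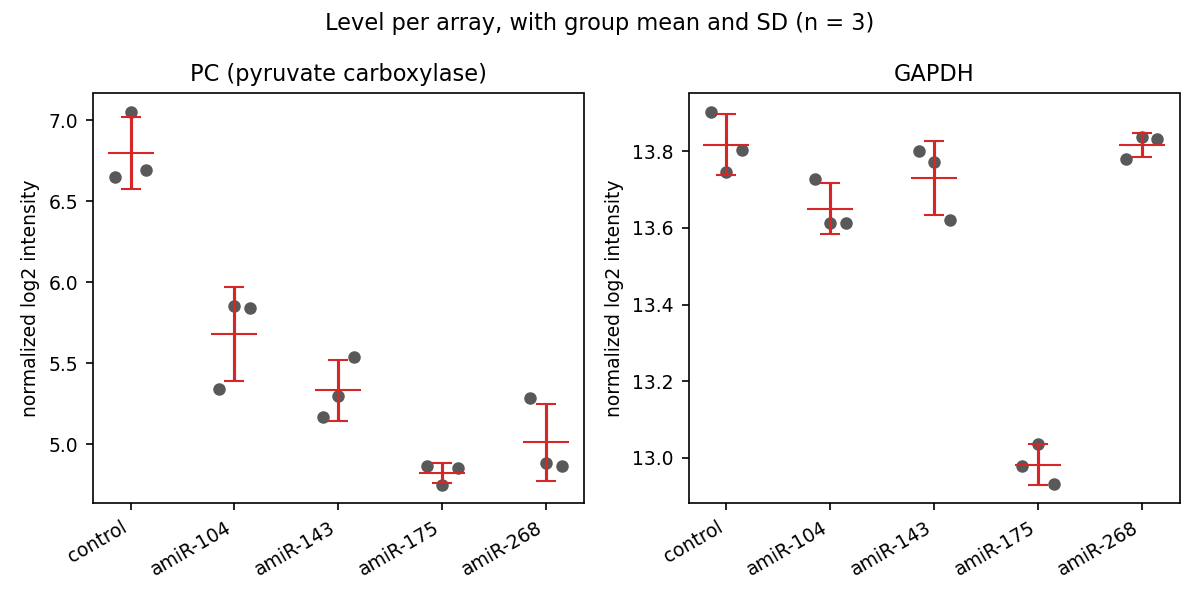
Normalized log2 intensity of the brightest PC probe (left) and the brightest GAPDH probe (right) on each of the 15 arrays, by group; points are arrays, horizontal bars are group means and error bars are SD (n = 3). All 12 amiR arrays lie below the 3 control arrays for PC, and the amiR-175 arrays lie below all others for GAPDH (log2 difference from the control −0.84).

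PC with amiR-104 was higher than with amiR-175 by 0.86 ± 0.16 (log2, SE, adjusted p = 0.000982, a bound of at least 1.38-fold) and than with amiR-268 by 0.67 ± 0.16 (adjusted p = 0.00675). PC was at least 1.09-fold higher with amiR-143 than with amiR-175 (adjusted p = 0.0212), a call that was lost with the authors' processed values, without background correction, with an offset of 50, with a trended and robust prior, without amiR-143 replicate 3 and without amiR-175 replicate 2. The other PC probes did not pass in that comparison. The PC differences between amiR-104 and amiR-143 (0.35), amiR-143 and amiR-268 (0.32) and amiR-175 and amiR-268 (−0.19) did not pass the test. Among these comparisons a call was gained 1 time under another setting and 2 times with an array left out. The size of the fall depended on the treatment of background: with the authors' processed values, from which no background is removed, the PC differences were −0.42, −0.52, −0.67 and −0.61, all with adjusted p of at most 0.00405.

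The next question was which other genes changed with each amiR. At an adjusted p under 0.05, 2797 of the 12395 genes changed with amiR-104 (1359 lower, 1438 higher), 5206 with amiR-143 (2521 lower, 2685 higher), 3887 with amiR-175 (1973 lower, 1914 higher) and 3342 with amiR-268 (1617 lower, 1725 higher). Changes of at least 2-fold were fewer: 208 lower and 115 higher with amiR-104, 540 and 483 with amiR-143, 396 and 169 with amiR-175, and 196 and 174 with amiR-268.

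**Figure D2:**
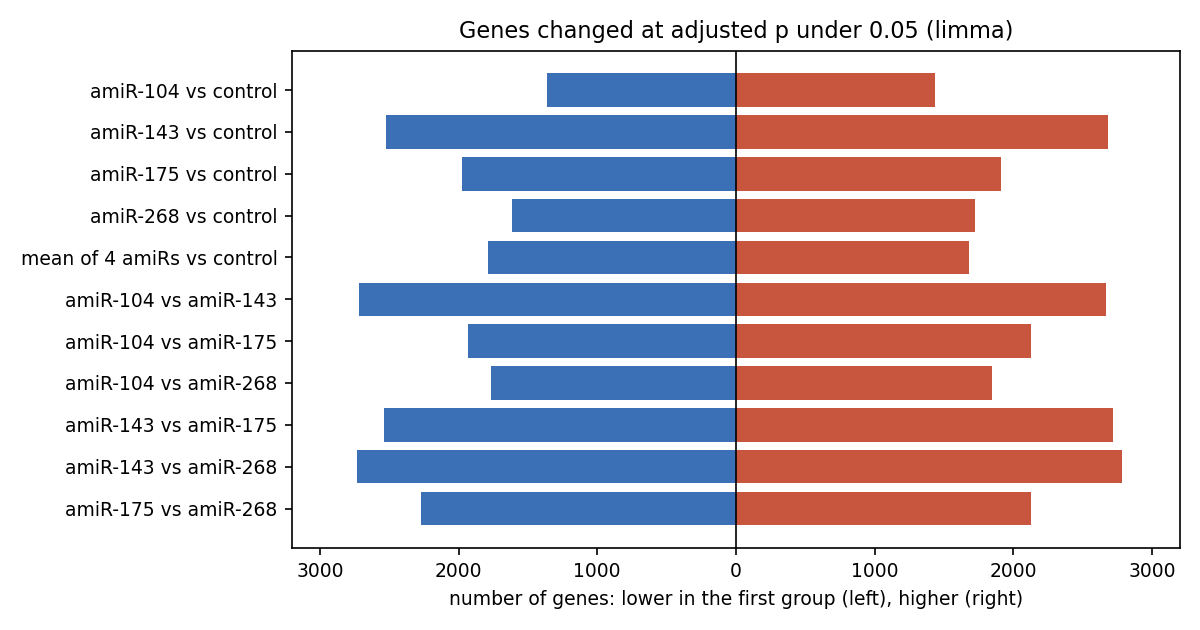
Number of genes lower (left, blue) and higher (right, red) in the first group of each of the 11 comparisons, at a limma adjusted p under 0.05 among 12395 genes; the horizontal axis starts at 0 in the middle and counts genes in both directions. Of the comparisons with the control, amiR-143 has the longest bars (2521 lower, 2685 higher) and amiR-104 the shortest (1359 lower, 1438 higher).

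With amiR-104, the lowest transcript relative to the control was FLOT2, a scaffold protein of membrane microdomains, at a log2 difference of −3.31 ± 0.11 (SE, adjusted p = 3.72e-10). Of 15 measured replication histone genes 9 rose, and of 36 genes of the G1/S transition and DNA replication 11 fell (adjusted p = 0.136 with an estimated correlation). Among the genes that changed, FLOT2 was followed by SIDT2, a lysosomal membrane protein (−2.35), WDR83OS (−2.22), ARF3, a small GTPase of the Golgi (−2.16), BSN, a scaffold of the presynaptic active zone (−2.10), TRIB3, a stress-induced pseudokinase (−2.10), CHMP4B, a subunit of the ESCRT-III complex (−2.06), IGDCC3 (−2.02), SDHD, a subunit of succinate dehydrogenase (−1.99), POLR2C, a subunit of RNA polymerase II (−1.98), MAVS, the mitochondrial adaptor of RNA sensing (−1.97), and JPT1 (−1.96). MAVS was detected on 2 of the 3 amiR-104 arrays. At the other end stood the histone genes H2BC5 (2.82), H2AC18 (2.66), H2AC19 (2.38), H2BC11 (2.12), H1-2 (1.91) and H2AJ (1.89), with TMEM31 (2.19) and the antisense RNA HDHD5-AS1 (2.13). Several histone genes have nearly identical copies, and a probe cannot always tell them apart, so the identity of the single histone genes is uncertain here and below. A second probe of HDHD5-AS1 did not pass the test.

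Of 15 measured genes on the replication histone list, 9 rose with amiR-104 and none fell, and 11 rose and 1 fell when adjusted over the list alone. The list median was 0.73, and camera placed it above the other genes (adjusted p = 3.39e-07, and adjusted p = 0.01 with an estimated correlation). With the authors' processed values, from which no background is removed, the histone medians were 0.26, 0.24, 0.28 and 0.18 with amiR-104, amiR-143, amiR-175 and amiR-268, and 0.29 in their mean. Of 36 G1/S and DNA replication genes, 11 fell and none rose (12 fell when adjusted over the list alone), among them MCM6, a subunit of the replicative helicase (−0.91), CDCA7 (−0.74), RRM2, a subunit of ribonucleotide reductase (−0.61), and CCNE1, cyclin E1 (−0.58). Another probe of CDCA7 and of CCNE1 did not pass. The camera adjusted p was 0.00238, and adjusted p = 0.136 with an estimated correlation. Of 22 p53 targets, 7 fell and 2 rose (9 and 2 when adjusted over the list alone), with PHLDA3 at −1.30, TP53I3 at −1.14, CDKN1A, the cyclin-dependent kinase inhibitor p21, at −1.09 and TP53INP1 at −1.07. This list had a camera adjusted p of 0.00356, and adjusted p = 0.0544 with an estimated correlation. Of 7 measured fibroblast markers, LOX (−1.15), TAGLN (at least 1.62-fold) and ACTA2 (−0.73) fell, and 3 fell when adjusted over the list alone (camera adjusted p = 0.0244, and adjusted p = 0.196 with an estimated correlation). Another TAGLN probe did not pass, and without the detection filter the median of the fibroblast markers was 0.02 in place of −0.33, with a camera adjusted p of 0.234.

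amiR-143 changed more genes than any other amiR. GDF15, a secreted stress-response cytokine, rose by 4.19 ± 0.19 (log2, SE, adjusted p = 1.33e-09) from a level detected on 1 of the 3 control arrays, and CCND1, which encodes cyclin D1, fell by 3.01 on the log2 scale (SE 0.13, adjusted p = 6.81e-10). Of 41 measured genes of G2/M and mitosis 28 rose (adjusted p = 0.0613 with an estimated correlation), and of 18 genes of cholesterol synthesis 12 fell (adjusted p = 0.0544 with an estimated correlation). The 12 lowest changed genes were NETO2, an auxiliary subunit of kainate receptors (−3.37), LRATD2 (−3.04), CCND1, MARCKSL1 (−2.87), HES5, a Notch target (−2.79), RAB5C, a GTPase of early endosomes (−2.74), THEM6 (−2.72), CDC42, a GTPase of cell polarity (−2.71), PRPS1, which makes phosphoribosyl pyrophosphate (−2.63), KCTD12 (−2.59), NUP210, a nuclear pore protein (−2.57), and AK4, a mitochondrial adenylate kinase (−2.50). One of the other CDC42 probes did not pass the test, and HES5 was detected on 1 of the 3 amiR-143 arrays. Beside GDF15, the genes that rose most were CCN1, a matricellular protein (3.61), KRTAP21-2 (at least 10.4-fold), H2AC18 (3.43), the kinase gene SGK1 (3.37), GPR162 (3.31), ANXA1, annexin A1 (at least 7.86-fold), and ANKRD1 (3.11). KRTAP21-2 and ANXA1 were not above background on any control array, and ANKRD1 was on 1.

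With amiR-143, 28 of 41 G2/M and mitosis genes rose and 2 fell (29 and 2 when adjusted over the list alone). NDC80, a kinetochore protein, rose by 1.30, CENPA, the centromeric histone H3 variant, by 1.12, NUSAP1 by 1.10 and the phosphatase CDC25C by 0.87. The camera adjusted p was 1.43e-06, and adjusted p = 0.0613 with an estimated correlation. Of 36 G1/S and DNA replication genes, 15 fell and 2 rose, the same counts as when adjusted over the list alone, with RFC5 at −1.65 and POLD1 at −1.03 (camera adjusted p = 0.00356, and adjusted p = 0.148 with an estimated correlation). Of 22 p53 targets, 13 rose and 2 fell by either adjustment, over all genes or adjusted over the list alone. TP53I3 (1.63), DDB2 (1.28) and GADD45A (1.17) were among those that rose, and CCNG1 was at −1.63 (camera adjusted p = 0.00445, and adjusted p = 0.0561 with an estimated correlation). Of 17 apoptosis regulators, 10 rose and none fell (11 and none when adjusted over the list alone), both promoters and inhibitors of apoptosis. They included BMF (at least 2.16-fold) and PMAIP1 (1.10), which promote it, and BCL2 (1.26) and BCL2L1 (1.06), which restrain it in its long form. This list had a camera adjusted p of 0.0059, and adjusted p = 0.0613 with an estimated correlation. Among the genes of this paragraph, another probe of CDC25C and of BCL2 did not pass.

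Interferon and dsRNA response genes were higher with amiR-143 in 13 of 25 cases and lower in 2 (14 and 2 when adjusted over the list alone). IFITM1 rose by 1.72, IRF9 by 1.04, IFITM2 by 1.01 and the peptide transporter gene TAP1 by 0.96 (camera adjusted p = 0.0188, and adjusted p = 0.0777 with an estimated correlation). Of 18 genes on the cholesterol synthesis list, 12 fell and 2 rose (12 and 3 when adjusted over the list alone). Among those that fell were MSMO1 (−1.60), DHCR7 (−1.40), NSDHL (−0.85) and INSIG1, a regulator of the pathway (−1.23). The list had a camera adjusted p of 0.00268, and adjusted p = 0.0544 with an estimated correlation. Of 18 glycolysis genes, 10 fell and 1 rose (11 and 1 when adjusted over the list alone), with PFKL at −1.69, HK2 at −1.31, ALDOA at −0.99 and TPI1 at −0.92 (camera adjusted p = 0.00238, and adjusted p = 0.37 with an estimated correlation). Of 22 genes of glutamine and glutamate metabolism, 11 fell and 3 rose by either adjustment, over all genes or adjusted over the list alone. PYCR1 was at −1.74, GLUD1, glutamate dehydrogenase, at −1.56, PFAS at −1.31 and CTPS1 at −0.89 (camera adjusted p = 0.0308, and adjusted p = 0.253 with an estimated correlation). Replication histones rose in 8 of 15 cases and fell in none, by either adjustment, over all genes or adjusted over the list alone (median 0.78, camera adjusted p = 0.000424, and adjusted p = 0.0428 with an estimated correlation). Another probe of MSMO1 and of ALDOA did not pass.

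**Figure D3:**
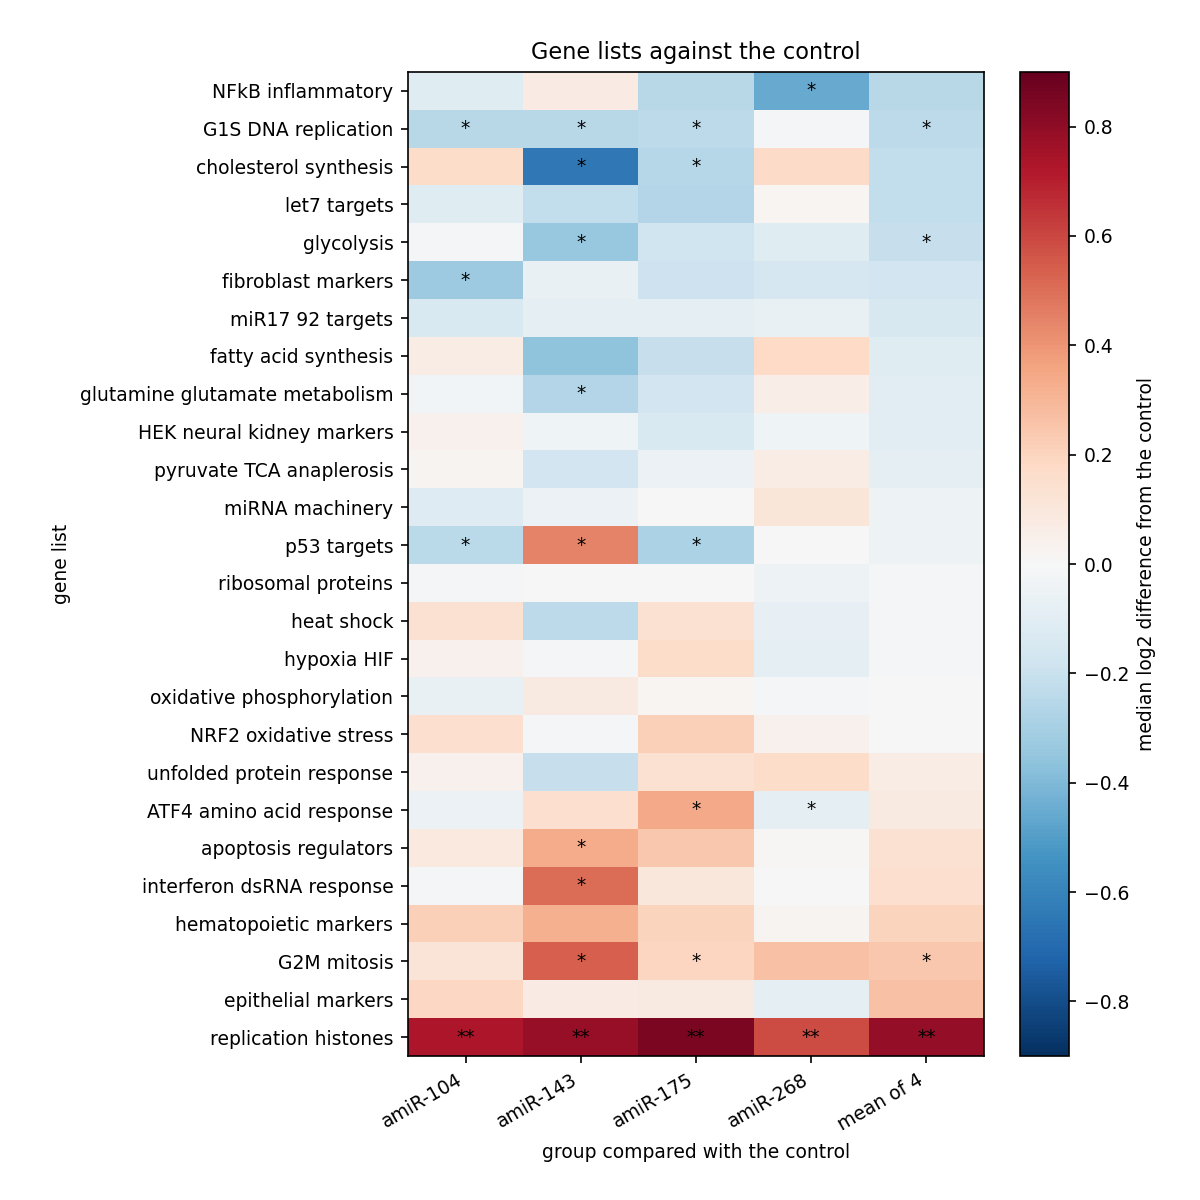
Median log2 difference from the control of each of the 26 gene lists (rows) in the 4 amiR groups and in their mean (columns), from blue (lower) to red (higher). One star marks a camera adjusted p under 0.05 with the preset correlation, and a pair of stars marks lists that also passed with an estimated correlation; replication histones passed both in every column, with medians from 0.59 to 0.85.

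With amiR-175, RPL23A, a protein of the large ribosomal subunit, was the lowest transcript, at −3.39 ± 0.10 (log2, SE, adjusted p = 7.4e-11), and ETV5, an ETS-family transcription factor that was not above background in the control, was at least 9.51-fold higher (adjusted p = 4.26e-09). Small nuclear and small Cajal body RNAs were among the transcripts that rose most. GAPDH, a glycolytic enzyme often used as a reference gene, fell by 0.84 on the log2 scale (SE 0.09, adjusted p = 6.14e-06), and was chosen for description after its values were seen. RPL23A rested on 1 probe. After it came DPM2, a subunit of dolichol-phosphate mannose synthase (−2.73), DPP3, a dipeptidyl peptidase (−2.71), TMEM150A (−2.69), CRTAP (−2.65), ATP6V0E2, a subunit of the vacuolar ATPase (−2.53), NPTX1, a neuronal pentraxin (−2.48), EI24 (−2.25), SH3GL1, an endophilin (−2.17), RRM2 (−2.12), PPP2R5A, a regulatory subunit of phosphatase PP2A (−2.10), and TMEM198 (at least 3.33-fold lower). Another CRTAP probe was called in the opposite direction. Beside ETV5, the genes that rose most were RNU4-1 (3.34), LY6G6D (2.94), RNU4-2 (2.88), SCARNA11 (2.56), SNORA12 (2.53), ZCCHC12 (2.46) and SCARNA16 (2.44). RNU4-1 and RNU4-2 are nearly identical copies of the U4 RNA of the spliceosome, so their identity is uncertain too, and RNU4-1 was detected on 1 of the 3 control arrays. The other 2 GAPDH probes gave −1.02 and −1.14 with amiR-175, while on the brightest probe GAPDH was at −0.17, −0.09 and 0.00 with amiR-104, amiR-143 and amiR-268, none of which passed the test. A further GAPDH probe did pass with amiR-104, at −0.34.

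Of 26 genes of the ATF4 amino acid response, 13 rose with amiR-175 and 2 fell (15 and 3 when adjusted over the list alone), including SLC7A11, the cystine transporter (1.67), its partner subunit SLC3A2 (0.96), DDIT4 (0.82) and ASNS, asparagine synthetase (0.60). The camera adjusted p was 0.00269, and adjusted p = 0.148 with an estimated correlation. Of 36 G1/S and DNA replication genes, 13 fell and 3 rose (14 and 4 when adjusted over the list alone), with GINS2 at −1.38, GINS3 at −1.31 and CCNE1 at −1.20 beside RRM2 (camera adjusted p = 0.00445, and adjusted p = 0.149 with an estimated correlation). Of 22 p53 targets, 9 fell and 1 rose (11 and 1 when adjusted over the list alone), with CDKN1A at −1.98, PHLDA3 at −1.45, AEN at −1.15 and BAX, of which another probe did not pass, at −0.89 (camera adjusted p = 0.00593, and adjusted p = 0.0613 with an estimated correlation). Of 41 G2/M and mitosis genes, 16 rose and 5 fell (17 and 6 when adjusted over the list alone), with ANLN at 0.72 and NEK2 at 0.66 (camera adjusted p = 0.0456, and adjusted p = 0.405 with an estimated correlation). Of 18 cholesterol synthesis genes, 4 fell and 2 rose by either adjustment, over all genes or adjusted over the list alone. TM7SF2 was at −1.28 and IDI1 at −0.95 (camera adjusted p = 0.0308, and adjusted p = 0.126 with an estimated correlation). Replication histones rose in 9 of 15 cases and fell in none, by either adjustment, over all genes or adjusted over the list alone (median 0.85, camera adjusted p = 3.03e-05, and adjusted p = 0.0203 with an estimated correlation).

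With amiR-268, the lowest transcript was SEPTIN9, a filament-forming GTPase of the cytoskeleton, at −2.21 ± 0.12 (log2, SE, adjusted p = 5.64e-08), and the highest was SYT11, a synaptotagmin of vesicle traffic, at 3.09 ± 0.18 (adjusted p = 7.19e-08). Of 15 measured replication histone genes 9 rose, and of 8 genes of NF-kappaB and inflammatory signalling 4 fell (adjusted p = 0.379 with an estimated correlation). SEPTIN9 was followed by TMEM150A (−2.16), R3HDM4 (−2.15), SRM, spermidine synthase (−2.11), VPS9D1-AS1 (−2.10), PEDS1, a desaturase of plasmalogen synthesis (−2.05), HSD17B10, a mitochondrial dehydrogenase (−2.03), JMJD4 (−2.00), TMEM9B (−1.99), CPLX1, complexin 1 of the presynaptic terminal (at least 3.24-fold lower), UCP2, a mitochondrial carrier (−1.87), and TAX1BP3 (−1.87). SYT11 was followed by H2BC5 (2.53), HDHD5-AS1 (2.33), SCARNA8 (2.26), NHLRC3 (2.22), SCARNA9 (2.00), APOLD1 (2.00) and RNU1-3 (1.94), a copy of the U1 RNA gene. For HDHD5-AS1 and NHLRC3 a second probe did not pass the test, and APOLD1 was detected on 1 of the 3 control arrays.

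Of 8 measured genes of NF-kappaB and inflammatory signalling, 4 fell with amiR-268 and 1 rose by either adjustment, over all genes or adjusted over the list alone. NFKB2 (−0.88), IER3 (−0.83), NFKB1 (−0.57) and NFKBIA (−0.50) were those that fell (camera adjusted p = 0.0297, and adjusted p = 0.379 with an estimated correlation). Of 26 genes of the ATF4 amino acid response, 7 fell and none rose by either adjustment, over all genes or adjusted over the list alone. They included the tRNA synthetase genes WARS1 (−0.83) and AARS1 (−0.76) as well as PPP1R15A (−0.77) and CEBPB (−0.56), and the camera adjusted p was 0.0456, and adjusted p = 0.308 with an estimated correlation. Replication histones rose in 9 of 15 cases and fell in none, by either adjustment, over all genes or adjusted over the list alone (median 0.59, camera adjusted p = 1.31e-06, and adjusted p = 0.0101 with an estimated correlation). HSPA5, the chaperone BiP of the endoplasmic reticulum, rose by 1.82 while its fellow chaperone HYOU1 was at −1.10 and the transcription factor XBP1 at −0.98, and the list of unfolded protein response genes as a whole did not pass (camera adjusted p = 0.399). FTL, the ferritin light chain, was at −1.62 and HSPB1, a small heat shock protein, at −1.72.

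**Figure D4:**
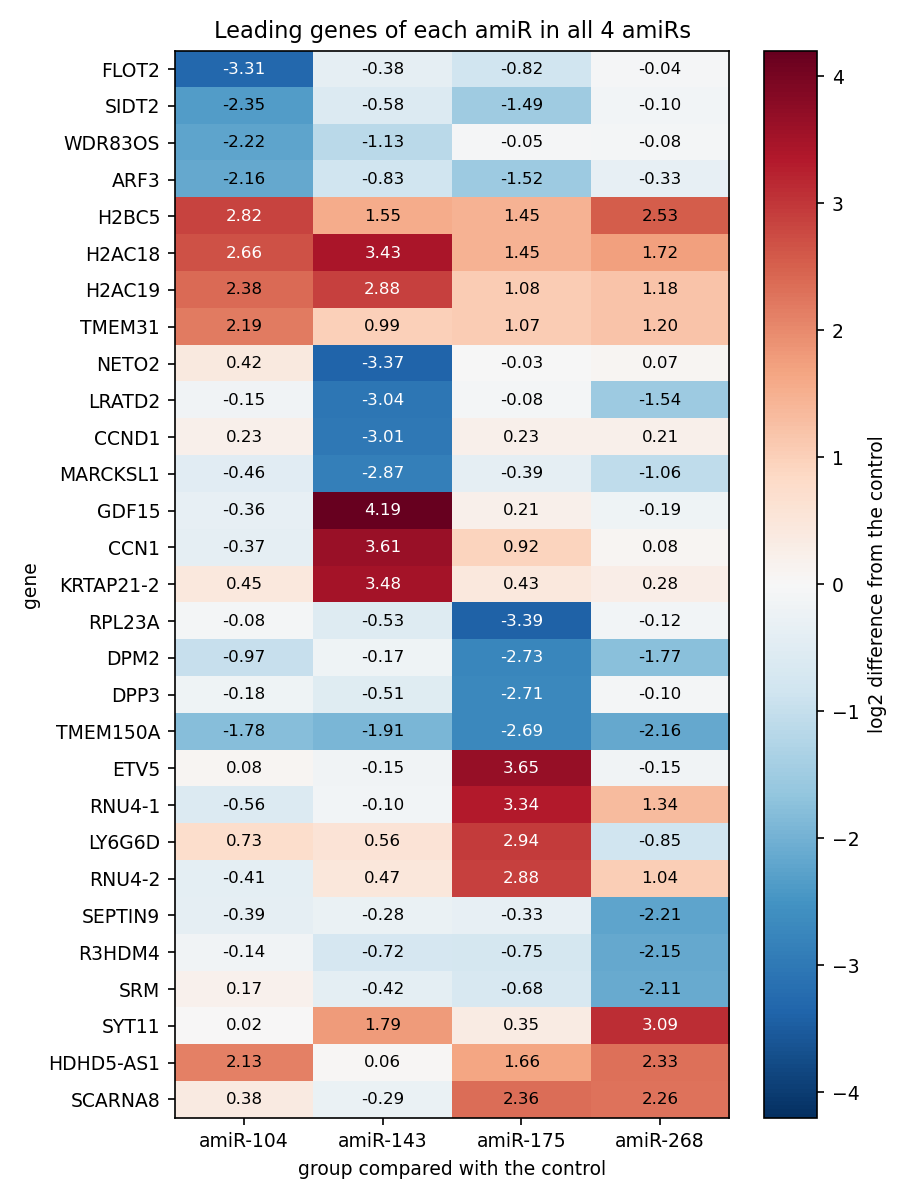
Log2 difference from the control (colour and printed value) in all 4 amiR groups (columns) of the genes that led each amiR in either direction (rows). FLOT2 is at −3.31 with amiR-104 and TMEM150A is low in all 4 columns (−1.78 to −2.69), while values drawn for genes at background in a group, such as ETV5 (at least 9.51-fold higher with amiR-175), are fitted values and not bounds.

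The mean of the 4 amiR groups was then set against the control, to find genes that moved on average over these amiRs. In such a mean opposite changes cancel, and a large change with 1 amiR can carry a gene. TMEM150A, a membrane protein, was the lowest at −2.14 ± 0.13 (log2, SE, adjusted p = 1.36e-07), and the histone gene H2AC18 the highest at 2.31 ± 0.08 (adjusted p = 7.27e-10). Of 12395 genes, 3468 changed (1787 lower, 1681 higher); the count was 2246 without control replicate 3. The same sign in all 4 amiRs was seen for 915 of the lower and 1171 of the higher genes. Next to TMEM150A stood CPLX1 (−1.71), CDK6, a kinase of the G1 phase (−1.59), PC (−1.58), PLPP3, a lipid phosphatase (−1.54), BSN (−1.50), NPTX1 (−1.48) and DPM2 (−1.41). The means of CPLX1 and PC are fitted values, not bounds, since CPLX1 was not above background with amiR-104 and amiR-268, nor PC with amiR-175. Next to H2AC18 stood H2BC5 (2.09), H2AC19 (1.88), H2BC11 (1.71), APOLD1 (1.58), SNORA28 (1.56), HDHD5-AS1 (1.54) and H2AC20 (1.47). Genes past the threshold in each of the 4 comparisons with the control numbered 111 lower and 204 higher, against 5.74 and 6.69 that independent lists of these sizes would share. All 4 comparisons use the same 3 control arrays, which those values leave out, so part of the excess may come from the shared controls. An effect of the siRNA or a shift of the control arrays would also move genes in all 4 comparisons. Neither can be told apart from an effect shared by the amiRs. Simulated unchanged groups gave a mean of 0 in either direction. With no gene changed few calls are made, so that 0 is no measure of the sharing among real calls. Those with the largest mean changes were TMEM150A, CPLX1, CDK6, PC and PLPP3 among the lower and H2AC18, H2BC5, H2AC19, H2BC11 and APOLD1 among the higher. CDK6 was at −0.85, −2.13, −1.97 and −1.42 with amiR-104, amiR-143, amiR-175 and amiR-268. The 111 became 22 and the 204 became 52 when a 1.5-fold change was also required, and 68 and 107 when only the groups compared entered each fit.

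In this mean, 9 of 15 replication histone genes rose and none fell (12 and none when adjusted over the list alone), with a camera adjusted p of 2.46e-08, and adjusted p = 0.00993 with an estimated correlation. Of 36 G1/S and DNA replication genes, 12 fell and none rose (14 and none when adjusted over the list alone), with CCNE1 at −0.72, RRM2 at −0.69, GINS3 at −0.61 and CDCA7, of which another probe did not pass, at −0.61 (camera adjusted p = 0.000192, and adjusted p = 0.0699 with an estimated correlation). Of 41 G2/M and mitosis genes, 17 rose and 4 fell (23 and 5 when adjusted over the list alone), with NUF2 at 0.85 and NDC80 at 0.76 (camera adjusted p = 0.00268, and adjusted p = 0.196 with an estimated correlation). Of 18 glycolysis genes, 8 fell and 1 rose (10 and 1 when adjusted over the list alone), with PFKL at −0.69 and the glucose transporter gene SLC2A1 at −0.53, and ENO2 at 0.68 as the one that rose (camera adjusted p = 0.00542, and adjusted p = 0.431 with an estimated correlation).

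No other list passed in the mean, and 14 of the 26 lists passed in none of the 5 comparisons. Among them, 8 of 33 genes of pyruvate metabolism and the TCA cycle fell in the mean and 2 rose (camera adjusted p = 0.117). Genes of oxidative phosphorylation moved little: 2 of 41 rose and 2 fell (adjusted p = 0.908). Of 16 unfolded protein response genes 5 rose and 3 fell (adjusted p = 0.94), of 15 heat shock genes 4 fell (adjusted p = 0.469), of 13 fatty acid synthesis genes 4 fell and 1 rose (adjusted p = 0.285) and of 19 hypoxia response genes 5 fell and 3 rose (adjusted p = 0.745). Among markers of other cell types, 2 of 8 for blood cells rose (adjusted p = 0.248) and 3 of 6 for epithelial cells rose (adjusted p = 0.44). Of 14 neural and kidney markers of this cell line 2 rose and 3 fell (adjusted p = 0.69). Fibroblast markers, which passed with amiR-104, held 1 gene of 7 that fell in the mean, LOX at −0.83 (adjusted p = 0.61). For these lists the counts were the same when adjusted over the list alone. Ribosomal protein genes showed 6 of 45 lower (5 when adjusted over the list alone, adjusted p = 0.406). Of 26 genes of the miRNA machinery 6 rose and 5 fell (6 and 6 when adjusted over the list alone, adjusted p = 0.92), with AGO1, an Argonaute protein that binds miRNAs, at −1.35. Of 14 let-7 targets 5 fell and 1 rose (8 and 2 when adjusted over the list alone, adjusted p = 0.0575), of 18 targets of the MIR17HG cluster 4 fell and 3 rose (5 and 3 when adjusted over the list alone, adjusted p = 0.399), and of 15 NRF2 targets 5 rose and 2 fell (7 and 3 when adjusted over the list alone, adjusted p = 0.592). All adjusted p values of this paragraph are from camera.

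The amiRs were last compared with one another, which leaves out the shared control arrays. The direct comparisons gave 5383 changed genes between amiR-104 and amiR-143, 4057 between amiR-104 and amiR-175, 3612 between amiR-104 and amiR-268, 5262 between amiR-143 and amiR-175, 5514 between amiR-143 and amiR-268 and 4400 between amiR-175 and amiR-268. GDF15 was higher with amiR-143 than with each other amiR: by at least 15.4-fold against amiR-104, by 3.98 (log2) against amiR-175 and by at least 15.6-fold against amiR-268. CCN2 was lower with amiR-104 than with amiR-143 (−4.00), as was CCN1 (−3.98), while NETO2 (3.80), CCND1 (3.24) and HES5 (3.22) were higher. Against amiR-175, amiR-104 had lower RNU4-1 (at least 10.2-fold), ETV5 (at least 9.43-fold) and RNU4-2 (−3.29) and higher RPL23A (3.31), FAM89B (2.82) and UFSP1 (2.64). Against amiR-268, amiR-104 had lower FLOT2 (−3.27), SYT11 (−3.07) and SCARNA9 (−2.98) and higher TMEM9B (2.75), FTL (2.29) and LHPP (2.29). Set against amiR-175, amiR-143 had higher CCN2 (3.18) and CDKN1A (3.06) besides GDF15, and lower ZCCHC12 (−4.05), ETV5 (at least 9.51-fold) and RNU4-1 (−3.44). Set against amiR-268, it had higher CCN1 (3.52) and ANXA1 (at least 7.89-fold) and lower NETO2 (−3.45), CCND1 (−3.22) and AK4 (−3.20). Between amiR-175 and amiR-268, ETV5 (at least 9.55-fold), LY6G6D (at least 10.5-fold) and TMEM9B (2.90) were higher and RPL23A (−3.28), RPS6KA2 (−2.96) and ATP6V0E2 (−2.76) lower with amiR-175. Another probe of RPS6KA2 did not pass.

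The lists were tested in these direct comparisons too, where 26 of 156 tests passed and 2 of these passed with an estimated correlation as well, both of them p53 targets. Those and 3 others are given here. Targets of p53 were lower with amiR-104 than with amiR-143 (median −0.66, camera adjusted p = 0.000214, and adjusted p = 0.0418 with an estimated correlation) and higher with amiR-143 than with amiR-175 (median 0.68, camera adjusted p = 8.62e-05, and adjusted p = 0.0418 with an estimated correlation). G2/M and mitosis genes were higher with amiR-143 than with amiR-104 (median of amiR-104 minus amiR-143 −0.38, camera adjusted p = 1.41e-05, and adjusted p = 0.109 with an estimated correlation). Genes of the ATF4 response were higher with amiR-175 than with amiR-268 (median 0.54, camera adjusted p = 2.63e-05, and adjusted p = 0.109 with an estimated correlation), and cholesterol synthesis genes were lower with amiR-143 than with amiR-268 (median −0.60, camera adjusted p = 0.0163, and adjusted p = 0.109 with an estimated correlation).

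The calls against the control were also set against each other. Genes that changed in the same direction numbered 1158 for amiR-104 and amiR-143 (538 lower, 620 higher), 1143 for amiR-104 and amiR-175 (540 and 603), 1026 for amiR-104 and amiR-268 (412 and 614), 1747 for amiR-143 and amiR-175 (876 and 871), 1283 for amiR-143 and amiR-268 (606 and 677) and 1211 for amiR-175 and amiR-268 (565 and 646). Independent lists of these sizes would share 276 lower and 311 higher, 216 and 222, 177 and 200, 401 and 415, 329 and 374, and 257 and 266 genes in the same order. Opposite directions were called for 472, 269, 263, 509, 582 and 340 genes, fewer than the 587, 439, 377, 817, 701 and 524 of independent lists. For each gene called in opposite directions the direct test between the pair of amiRs also passed. The direct difference adds both sizes at the same standard error, so that outcome was all but fixed beforehand and adds no support. Simulated unchanged groups set against the same controls shared a mean of 0 calls, but with no gene changed few calls are made, so this is no measure of the sharing to be had among real calls. Across genes, which are not independent replicates, the log2 differences of each pair correlated at 0.248, 0.349, 0.373, 0.337, 0.234 and 0.348. Shared controls alone gave about 0.50 in the simulation, where no gene changed. Changes particular to 1 amiR add variance and lower a correlation, so that 0.50 is no yardstick for these values. The covariances were 0.0579, 0.0667, 0.0629, 0.0929, 0.057 and 0.0695, against simulated values of 0.0137 to 0.0138. The simulated covariances already hold the noise of the shared controls. That noise alone does not account for the excess over them, 0.0433 to 0.0792. A shift common to the 3 control arrays, which are too few to be split, may still give part of it. The numbers for independent lists leave out the shared controls, so part of the excess in shared genes may come from them.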

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

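The tests of S phase, of arrays of like brightness, of RNA without poly(A) tails, of low control arrays, of a faulty GAPDH probe and of the other glycolysis genes were chosen after the result was seen. Outside the genes tested, 5991 probes passed the detection filter without a single gene symbol in the annotation used. Of these, 370 changed with amiR-104, 850 with amiR-143, 582 with amiR-175 and 479 with amiR-268.

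Replication histone genes were higher than in the control with each of the 4 amiRs, with list medians of 0.73, 0.78, 0.85 and 0.59. A rise of the G1/S and DNA replication genes was taken as the sign of more cells in S phase. Their median in the mean of the 4 amiRs was −0.24 (camera adjusted p = 0.000192, and adjusted p = 0.0699 with an estimated correlation). For amiR-268 alone it was −0.018 (camera adjusted p = 0.66). These genes need not peak together with the histone genes, and their fall did not pass with an estimated correlation. More cells in S phase therefore cannot be told apart from other causes. Of 4 other scalings, median scaling alone replaces quantile normalization, and the rest keep it and vary the background treatment. Under all of them the lowest histone median was 0.29 in the mean and 0.26, 0.24, 0.28 and 0.18 in the single amiRs. The rise thus held under median scaling, which argues against quantile normalization as its source. A general rise of RNA without poly(A) tails is argued against for amiR-104, where small nuclear and nucleolar RNAs had a median of −0.091, and it stays open for the other amiRs. A shift of the 3 control arrays for a reason other than the siRNA cannot be told apart from an effect of the amiRs or of the siRNA, since all controls share 1 group: the lowest amiR array lay 0.58 above the highest control array in mean log2 of the list.

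Small nuclear and nucleolar RNAs, chosen as a group after their values were seen and counted with the genes that prompted the choice, were higher than in the control with amiR-175 (63 of 173 rose and 11 fell, camera p = 1.28e-05, and p = 0.0916 with an estimated correlation) and amiR-268 (48 rose and 15 fell, camera p = 0.000971, and p = 0.189 with an estimated correlation), while with amiR-104 11 rose and 29 fell (camera p = 0.0295, and p = 0.374 with an estimated correlation) and with amiR-143 44 rose and 24 fell (camera p = 0.113). Without the 9 that were among the leading genes of any comparison, 54 of 164 rose and 11 fell with amiR-175 (camera p = 0.000286, and p = 0.116 with an estimated correlation), and 39 rose and 15 fell with amiR-268 (camera p = 0.0093, and p = 0.246 with an estimated correlation). Values near background are argued against by the lower of the medians, 0.27, among the 81 members detected on all arrays. Of 4 other scalings, median scaling alone replaces quantile normalization. Under it the medians were 0.29 with amiR-175 and 0.27 with amiR-268, which argues against quantile normalization as the source. The rest vary the background treatment, with a lowest median of 0.089. Under these scalings camera p over all 173 was at most 0.00138, with the preset correlation only. A covariate for array brightness (lower median 0.22) moved too little to test it. Mean log2 of the small RNAs was also compared between each array and control arrays within 2.5% of its mean intensity. For amiR-175 the differences were 0.35, 0.43, 0.60 and 0.52, all above the largest SD of a group, 0.15, which argues against brightness there. For amiR-268 they ran from 0.13, below that SD, to 0.44, so brightness cannot be told apart from an effect of amiR-268. RNA quality and the labelling of short RNAs were not tested and stay open as well.

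GAPDH was lower with amiR-175 than in the control, and was chosen after its values were seen. A single faulty probe is argued against, since the least changed of 3 probes was at −0.84 and all 3 passed the test. Under 4 other scalings, of which median scaling alone replaces quantile normalization, the value nearest to 0 was −0.75. Neither quantile normalization nor the background treatment therefore accounts for the fall. The other measured glycolysis genes had a median of −0.15, which argues against a fall of the whole pathway by as much as GAPDH. Of all 18 glycolysis genes, GAPDH included, 7 fell with amiR-175 and 1 rose (camera adjusted p = 0.067, and adjusted p = 0.559 with an estimated correlation). A smaller fall of the pathway stays open. A seed match of amiR-175 in GAPDH was not tested and stays open.

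The numbers of changed genes were set against other splits of the arrays. For the mean of the 4 amiRs, 1 of 100 drawn splits of the 15 arrays into 3 and 12 gave as many genes as the real one, itself (3468, highest other 353). The other splits mix groups that differ, which widens their spread and lowers their counts, so this leaves open a shift shared by the control arrays. For 3 arrays against 3 the 10 splits are too few for a share under 0.05. In each comparison 1 split, the real one, gave as many genes as observed. Against the control the real values were 2797 for amiR-104, 5206 for amiR-143, 3887 for amiR-175 and 3342 for amiR-268, with highest others of 0, 0, 1 and 0. Between amiRs they were 5383 (amiR-104 and amiR-143), 4057 (amiR-104 and amiR-175), 3612 (amiR-104 and amiR-268), 5262 (amiR-143 and amiR-175), 5514 (amiR-143 and amiR-268) and 4400 (amiR-175 and amiR-268), with highest others of 0, 1, 0, 0, 0 and 0.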

How the results depend on the processing

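All alternatives were chosen before the data were examined. Of 596 named values past the threshold, 83 lost their call or reversed under at least 1 setting, and 3 of these reversed, all with the mean of a gene's detected probes: AGO3 with amiR-104 (−0.062), CNOT1 with amiR-143 (0.57) and ZMAT3 in the mean of the 4 amiRs (−0.028). That setting brings in other probes of these genes. The stricter thresholds and the test of each probe on its own were not applied to the named values, PC included. PC was lower with each amiR, past the threshold, under every setting that was applied to it. Without each array in turn its values were −1.21 to −0.95 with amiR-104, −1.56 to −1.34 with amiR-143, −2.05 to −1.85 with amiR-175 and −1.92 to −1.66 with amiR-268. With the authors' processed values they were −0.42, −0.52, −0.67 and −0.61. Signal over background limits such folds, since PC lies near background in the amiR groups and folds shrink where no background is removed.

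Requiring at least 1.5-fold left 1375, 3071, 2011 and 1598 genes for amiR-104, amiR-143, amiR-175 and amiR-268, 860 for their mean, and 3279, 2244, 1885, 3194, 3428 and 2403 for the pairs of amiRs in the order of the report. Genes changed in the same direction were then 432, 406, 369, 708, 472 and 450 per pair, with 22 lower and 52 higher in all 4. An adjusted p under 0.01 left 1563 for amiR-104, 2417 for amiR-175, 1916 for amiR-268, 1929 for the mean and 2355 for amiR-104 against amiR-268. Genes changed in the same direction were then 579, 532, 461, 958, 637 and 601, with 42 lower and 72 higher in all 4. These falls follow from stricter thresholds. With only the groups compared in each fit, 768 genes changed in the same direction with amiR-104 and amiR-143 and 678 with amiR-104 and amiR-268, and 68 were lower and 107 higher in all 4, with fewer arrays to estimate the spread. With median scaling 73 were lower in all 4, and the cause was not tested. With an estimated correlation 5 of 26 list calls passed, and 4 of 22 without the mean. Other settings ended at most 4 list calls each (stricter detection filter).

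Without each array in turn, the mean of the 4 amiRs gave 2246 to 3478 genes (lowest without control replicate 3) and genes higher in all 4 numbered 129 to 217 (lowest without control replicate 1). Counts for the single amiRs were 2176 to 2766, 4554 to 5337, 3166 to 3988 and 2610 to 3462, and genes lower in all 4 numbered 76 to 110.

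Whether the replicate numbers pair the samples was not settled. Deviations of arrays with the same number correlated at −0.0928 to 0.131 (median 0.0432), over 0.1 in 3 of 30 pairs. Those of arrays with different numbers correlated at −0.143 to 0.0919 (median −0.0177). As 9 of 15 arrays correlated best with their own number, a weak pairing stays open. With the replicate block the counts were 2837, 5227, 3899 and 3349 for the 4 amiRs and 3456 for the mean, 5429, 4080, 3575, 5305, 5541 and 4396 for the pairs, and 105 lower and 206 higher in all 4. PC stayed at −1.12, −1.46, −1.97 and −1.78, and 24 list calls passed, 20 without the mean. The slide as a block was not run because no slide is given, nor were any settings for the seed search.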

Other observations

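The lists of this part were written after the leading genes were seen and before their other members were tested. CCN1 (3.61), CCN2 (3.00) and ANKRD1 (3.11), which encode products raised by the transcription factors YAP and TEAD, rose with amiR-143. Of 17 other measured targets of these factors, 8 rose and 1 fell. TNFRSF12A was at 1.56, AJUBA at 1.17, GADD45A at 1.17 and NUAK2 at 1.09, and FJX1 at −1.65. Their median was 0.35 (camera adjusted p = 0.013, and adjusted p = 0.0661 with an estimated correlation), so a rise of YAP and TEAD targets with amiR-143 is a candidate explanation, found and tested on the same arrays.

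ETV5 (at least 9.51-fold) and DUSP5 (1.70), genes that ERK signalling raises, rose with amiR-175 and were left out of the test. Of 16 other measured genes of ERK feedback, EMP1 (1.20), DUSP6 (0.81) and SPRED1 (0.68) rose and EPHA4 (−0.72) and SPRY1 (−0.58) fell. Their median was 0.18 (camera adjusted p = 0.318, and 0.35 with an estimated correlation), so a shared rise cannot be told apart from its absence, as members went both ways.

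CPLX1 (a fitted −1.71, as it was not above background with amiR-104 and amiR-268), BSN (−1.50), NPTX1 (−1.48), CHGA (−1.16) and SYP (−1.13), genes of the synapse and of secretory vesicles, fell in the mean of the 4 amiRs and were left out of the test. Of 21 other measured genes of neuronal vesicles 4 rose and 5 fell, with VGF at −0.89 and INA at −0.62. Their median was −0.071 (camera adjusted p = 0.318, and 0.35 with an estimated correlation), so a shared fall cannot be told apart from its absence, as members went both ways.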
